A study of Mus musculus with 11 samples.

How the data were processed

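Single-cell RNA sequencing (10x Genomics 3' chemistry, version 3.1) was done, per the labels, on forelimbs of fetal mice at embryonic day 17.5, with 1 library for each of 11 embryos. The labels state that the forelimbs were trimmed of skin and paws and dissociated with collagenase and pronase in the presence of the transcription inhibitor actinomycin D. They also state that red cells were lysed, that dead cells were removed on magnetic columns, and that the cells were fixed in methanol while the embryos were genotyped. The steps of dissociation, dead cell removal and fixation set which cell types and which RNA reach a library, so the share of a cell type in the counts is not its share in the limb.

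The values are UMI counts per gene and barcode, as deposited by the authors, with no normalization. The submitters' processing notes and the file headers name Cell Ranger 6.0.0 and the mouse genome build mm10; the gene annotation and the settings for calling cells are not stated there. Each matrix held 32287 features, of which 32158 were matched by gene ID to GENCODE vM21 on GRCm38 (mm10), the annotation used here for positions. The features include the transgene sequences GFP and Cre-recombinase. In a check for duplicates the 15 pairs of libraries within a group were compared in each of 5 cell classes, 75 comparisons, and the chi-square per degree of freedom ran from 2.42 to 322, so no library repeated another of its group. Pairs between groups were not compared.

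The groups were taken from the labels. The libraries labelled WT(Osx-cre) (n = 4) are, per the labels, wild type for YAP and TAZ with the Osx-cre transgene, which drives Cre recombinase from the Osterix (Sp7) promoter. The libraries labelled WT(fl/fl) (n = 4) have, per the labels, floxed YAP and TAZ alleles and no Cre, and those labelled YAP/TAZ Osx-cKO, called cKO here (n = 3), the floxed alleles with Osx-cre. The labels were not tested beyond the transgene UMIs given in the results, which leave some in doubt. All WT(Osx-cre) libraries came from 1 litter and were made with single-index kits. All WT(fl/fl) libraries and cKO replicates 1 and 2 came from another litter and were made with dual-index kits. The cKO replicate 3 came from the remaining litter and a single-index kit. Genotype group, litter and kit therefore cannot be told apart between the control groups, and the replicate numbers of the labels do not stand for paired embryos.

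Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Predicted doublets were removed per library with the Scrublet method in scanpy 1.11.5. Where its automatic threshold marked under 0.5% of the cells, the highest scores were removed at 0.8% per 1000 cells. That replacement was used for WT(fl/fl) replicates 1 and 3 and cKO replicate 2, and the share removed ran from 1.59% in cKO replicate 3 to 11.8% in WT(fl/fl) replicate 1. In all, 122451 cells were kept. Counts were scaled to 10000 per cell and log transformed. For clustering, 3000 highly variable genes were taken, leaving out Yap1, Wwtr1, the YAP/TAZ target list, hemoglobin, mitochondrial and Y-linked genes and Xist. Clusters were found with 40 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 with 10 iterations (leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0), without batch correction. Of 49 clusters, 11 in which the osteoblast or periosteal score and the score of another class were at least 0.5 were clustered again on 1000 genes and 20 components, which gave 140 clusters.

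Clusters were named from fixed marker lists. The score of a class was the mean over its markers of the log2 level (prior of 10 CPM), centred and scaled over the clusters. A cluster took the name of the class with the highest score, if this was at least 0.8, if at least 3 markers were raised by a log2 ratio of 1 over the other clusters, and if its 10 leading genes held no marker of another class, or fewer of any other class than of its own. In this way 106 clusters were named, and 34 clusters with 27949 cells were not. A cluster with none of its own markers among the 10 leading genes could keep its name, as 5 did. They hold 410 and 240 synovial and articular-like, 167 fibroblast-like, 155 pericyte and smooth muscle-like and 114 chondrocyte-like cells, and 3 of them come almost wholly from cKO replicate 3 (238 of 240, 162 of 167 and 150 of 155 cells). The unnamed clusters held 18.4% ± 11.8 of the cells of WT(Osx-cre) libraries (mean ± SD, n = 4), 32.3% ± 16.6 in WT(fl/fl) (n = 4) and 25.5% ± 7.96 in cKO (n = 3). Clusters with a low score took 8.11% ± 2.54, 25.8% ± 18.2 and 21.8% ± 7.62 in the same order. The rule that a cluster with as many markers of another class as of its own stays unnamed was made after the clusters per library had been seen, before any expression test. It left out 3 clusters with 1050 cells, which held 0.957% ± 0.332 of WT(Osx-cre), 0.832% ± 0.947 of WT(fl/fl) and 0.410% ± 0.710 of cKO cells. Of these 1 was led by periosteal and a pair by osteoblast markers. Cell types are called osteoblast-like and so on, since they rest on marker RNA.

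For each library and class, the UMI counts of the cells were summed, and a library with under 20 cells of a class was left out of that class. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, two-sided), with all 3 groups in 1 model. The Benjamini-Hochberg adjustment ran over the genes tested, with a threshold of 0.05. The comparisons were cKO against the mean of both control groups in osteoblast-like, periosteal and osteoprogenitor-like, chondrocyte-like, blood endothelial-like and fibroblast-like cells, and the 3 pairwise comparisons in the osteoblast-like and periosteal and osteoprogenitor-like cells. Fold changes are on the log2 scale with their standard error (SE), and levels are TMM-normalised counts-per-million (CPM). Shares of each class among kept cells other than erythroid-like cells were compared with a two-sided exact permutation test over all 165 ways to choose 3 of 11 libraries, adjusted over 18 classes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.

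The 21 gene lists were YAP/TAZ targets, osteoblast maturation, osteoblast precursor, fibrillar collagen and matrix, angiogenic ligands, hypoxia and glycolysis, endothelial vessel type, cytoskeleton and adhesion, hypertrophic chondrocyte, resting and proliferating chondrocyte, osteoclast regulation, BMP, Wnt and Hedgehog response, S phase, G2 and M phase, interferon response, dissociation and stress, p53 and apoptosis, red blood cell RNA, heavy muscle RNA, epidermal RNA and cartilage RNA. They were tested in 4 classes with camera of limma 3.58.1 on voom log CPM with the preset correlation of 0.01, for lists with at least 3 measured genes. Camera compares a list with the other genes. It was run again with a correlation estimated per list, beside fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. List p-values were adjusted over the lists within a class. The genes named in the text follow a rule. In each class these were the genes past the threshold with a log2 change of at least 0.5 and 1 sign against each control group, 8 up and 8 down in the osteoblast-like and periosteal cells and 4 and 4 elsewhere. This ranking left out genes with under 0.2 of their level in another class, markers of other classes, hemoglobin, mitochondrial, ribosomal and Y-linked genes, Xist and clone names. Up to 4 members of each list with the smallest p, Yap1, Wwtr1, Cxcl12, Vegfa, Cxcr4 and Kdr were named in any case. Groups, tests, lists, the naming of genes and most alternatives were fixed before the data were examined.

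Alternatives set in advance were the DESeq2 1.42.0 Wald test, DESeq2 size factors, no filter on low counts, the replicate number as a block, the kit as a covariate, the shared litter alone, a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs), doublets kept, Leiden resolution 2, a graph with 2 neighbours from each library, clustering without the osteoblast and matrix lists, counts thinned to the smallest total, and each library left out in turn. For shares they were the log2 share, erythroid-like cells in the denominator and edgeR on cell counts. Fits without the 3 shallow dual-index libraries and on deep libraries alone were added after the planned test called few genes. So were fits with depth (shallow or deep) as a covariate, without cKO replicate 3 or in the shared litter alone. So was clustering without the osteoblast lists for gene counts. Shares among named cells, without those 3 libraries, and with clusters of tied markers counted under their leading class were added after the shares had been seen. Shallow libraries are the 4 with under 40 M (mega) UMIs.

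The test was run on simulated data with the sample sizes and totals of these libraries. Of 100 genes changed by a log2 fold of 1 and 100 by 2 in osteoblast-like sums, edgeR recovered 14 and 85. It made 7 false calls among 8636 genes. DESeq2 recovered 23 and 92 with 13 false calls. Rates may differ at low levels and under shifts between libraries. Ambient RNA, the RNA free in the droplets, was not subtracted. Where a count is 0, the floor of 3 counts is given as CPM, and such floors and intervals cover counting error only.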

Results

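The study measured RNA in single cells of the fetal mouse forelimb to ask, in the words of its title, about YAP and TAZ in osteoblast precursor mobilization, angiogenesis and mechanoregulation of fetal bone. YAP and TAZ, encoded by Yap1 and Wwtr1, are paralogous co-activators that carry Hippo pathway and mechanical signals to the nucleus. Libraries from 11 embryos of 3 litters fell into 3 groups: 4 labelled WT(Osx-cre), 4 labelled WT(fl/fl) and 3 labelled YAP/TAZ Osx-cKO (cKO), in which Cre under the Osterix promoter is meant to delete both genes in cells of the osteoblast lineage.

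Depth differed widely between libraries. The libraries labelled WT(Osx-cre) replicates 1 to 4 held 134.6, 74.6, 84.5 and 133.8 M UMIs (M, mega), those labelled WT(fl/fl) 92.7, 156, 29.2 and 29.9 M, and the cKO libraries 157, 17.7 and 17.3 M. After filtering, 12653, 10488, 10874 and 15115 cells were kept in WT(Osx-cre), 11265, 15743, 7918 and 9485 in WT(fl/fl), and 17829, 5680 and 5401 in cKO. The median UMIs per kept cell ran from 1541 in cKO replicate 2 to 8555 in WT(Osx-cre) replicate 1. Under 40 M UMIs lay 4 libraries, WT(fl/fl) replicates 3 and 4 and cKO replicates 2 and 3, so that 1 cKO library was deep.

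The kept cells took the names of 18 classes tested for share. Osteoblast-like cells, named by genes such as Ibsp and Ifitm5, numbered 68 to 223 per library, which gave between 0.287 and 2.70 M UMIs per sum. Periosteal and osteoprogenitor-like cells, called periosteal-like, numbered 151 to 577, chondrocyte-like cells 370 to 932, blood endothelial-like cells 214 to 1468 and fibroblast-like cells 539 to 4203. Osteoblast-like cells came from 1 shared cluster in every library, with a smaller cluster beside it. Periosteal-like and chondrocyte-like cells came mostly from different clusters in the deep libraries, in the 3 shallow dual-index libraries and in cKO replicate 3. Fibroblast-like cells were split in part: the main cluster of the shallow dual-index libraries also held 98 to 536 cells of each deep library, and 363 of the 773 cells of cKO replicate 3 shared a cluster with deep libraries. The largest endothelial-like cluster of the deep libraries held 2 to 9 cells of each shallow dual-index library. The other clusters were shared, except that 1 of them held 2 cells of cKO replicate 3 against 76 to 410 of each other library.

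The targeted genes were examined for every library. In osteoblast-like cells Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, GRCm38) stood at 19.0, 8.41, 9.53 and 15.9 CPM in the libraries labelled WT(Osx-cre), at 16.6, 18.8, 16.6 and 17.0 CPM in those labelled WT(fl/fl), and at 11.6, 4.08 and 37.6 CPM in cKO. Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910) stood at 47.7, 31.3, 26.2 and 45.4 CPM, at 39.3, 41.7, 12.4 and 37.4 CPM, and at 14.5, 32.7 and 15.0 CPM in the same order. Against both control groups the log2 change in cKO was 0.24 (SE 0.44, adjusted p = 0.934) for Yap1 and -1.02 (SE 0.38, adjusted p = 0.746) for Wwtr1, and neither passed the edgeR test. The sign of the Yap1 value rested on cKO replicate 3, without which it was -0.61. Yap1 changed by 0.62, 0.51, 0.57 and 0.39 and Wwtr1 by -0.36, -0.41, -0.22 and -0.07 in the periosteal, chondrocyte, endothelial and fibroblast classes. None of these 10 values passed, and 1 did without cKO replicate 1. The tags lie at the 3' end of each transcript, and a tag outside the deleted part of a gene does not report on its deletion.

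Transgene UMIs gave a further check of the labels. Cre UMIs were counted 13, 8 and 22 times in the cKO libraries, 43 in 192 M UMIs, of which 21 lay in osteoblast-like cells. In these cells they made up 4.28, 10.5 and 26.8 CPM. In the 4 libraries labelled WT(Osx-cre) 1 Cre UMI was found among 427 M, and none among the 6.35 M of their osteoblast-like cells, which allows up to 0.473 CPM. The libraries labelled WT(fl/fl) held none in 308 M UMIs, which allows up to 0.638 CPM in osteoblast-like cells. GFP UMIs numbered 64 and 149 in WT(fl/fl) replicates 3 and 4 and 93 in cKO replicate 2. They numbered 2 in cKO replicate 1, 1 in WT(Osx-cre) replicate 4 and 0 in the remaining libraries. In osteoblast-like cells GFP stood at 62.6 and 62.8 CPM in WT(fl/fl) replicates 3 and 4 and at 69.7 CPM in cKO replicate 2, against 1.22 and 0 in cKO replicates 1 and 3 and 0 in WT(fl/fl) replicates 1 and 2. The labels name no GFP transgene. GFP did not follow the Cre UMIs. At the Cre rate of cKO replicate 2, WT(fl/fl) replicates 3 and 4 together would hold 6.50 Cre UMIs in osteoblast-like cells and 26.8 over all barcodes, and 0 were seen. The Cre counts leave the WT(Osx-cre) label undecided, as an untranscribed or differently built transgene gives the same. GFP in WT(fl/fl) replicates 3 and 4 is unexplained, so groups below are named by label alone.

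**Figure D1:**
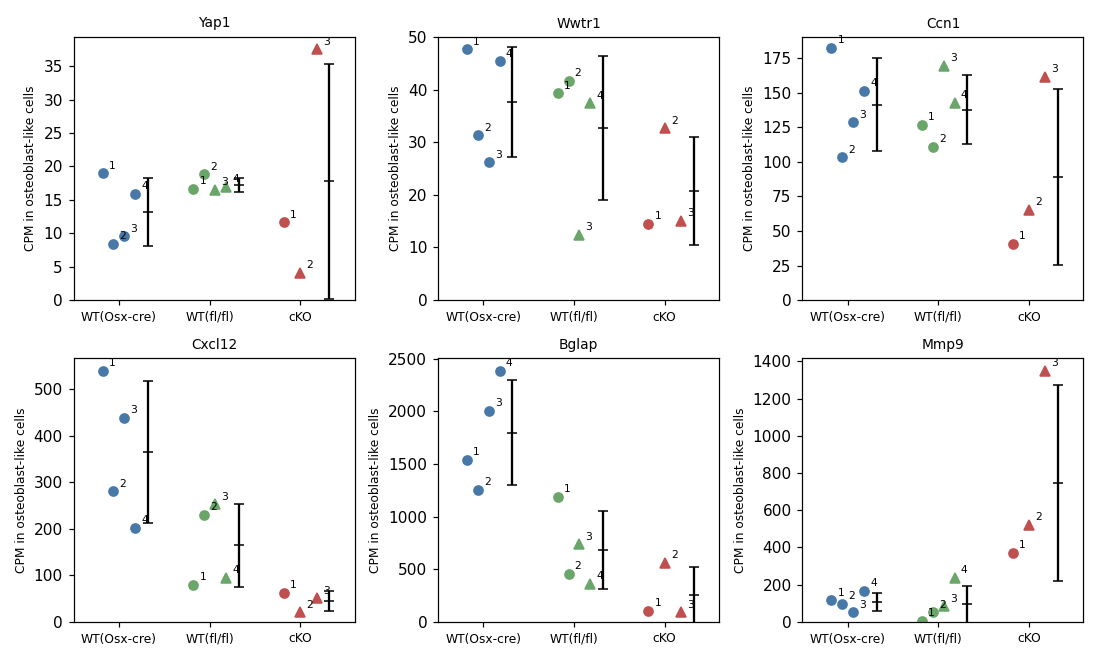
CPM of Yap1, Wwtr1, Ccn1, Cxcl12, Bglap and Mmp9 (vertical axes, linear and starting at 0) in summed osteoblast-like cells of each library, by group on the horizontal axis; triangles are libraries under 40 M UMIs, circles the others, numbers the replicates, and black marks the mean ± SD. The cKO libraries lie below all control libraries for Cxcl12 and above them for Mmp9, while the Yap1 value of cKO replicate 3, 37.6 CPM, lies above all others.

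The main comparison asks which RNA differs in osteoblast-like cells when YAP and TAZ are targeted in the Osterix lineage. Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), a chemokine that guides and retains cells through the receptor Cxcr4, was lower in each of the 3 cKO libraries than in any control. Its level was 365 ± 152 CPM in WT(Osx-cre) (mean ± SD, n = 4), 164 ± 89.3 in WT(fl/fl) (n = 4) and 44.4 ± 21.6 in cKO (n = 3). Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464), which encodes osteocalcin, the secreted protein of mature osteoblasts, stood at 1797 ± 499.7, 685 ± 369.8 and 251 ± 267. Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850), a gelatinase of osteoclasts and of cells that invade cartilage, was higher in 3 of 3 cKO libraries than in any control, at 747 ± 527 against 107 ± 48.4 and 94.5 ± 101 CPM. Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), the main growth factor of endothelial cells, differed less between the groups than within cKO, at 36.8 ± 3.07, 32.3 ± 4.07 and 44.4 ± 33.2 CPM.

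No gene passed the planned edgeR test in osteoblast-like cells in cKO against both controls: 0 of 8941 genes had an adjusted p under 0.05, and 565 had an unadjusted p under 0.05. The DESeq2 test called 6 genes higher and 8 lower. Among the latter were Cxcl12 (log2 -2.35, adjusted p = 0.00127) and Bglap (log2 -2.14, adjusted p = 0.0215, lower in 3 of 3 cKO libraries than the mean of either control group). In edgeR Cxcl12 had a log2 change of -2.37 (SE 0.49, adjusted p = 0.202) and Bglap -2.18 (SE 0.59, adjusted p = 0.432). Over the alternatives the adjusted p ran from 0.000124 to 1 for Cxcl12 in osteoblast-like cells and from 0.00366 to 1 for Bglap in osteoblast-like cells, with the sign kept in each. Mmp9 had a log2 change of 2.93 (SE 0.59, adjusted p = 0.196), and its level in these cells was 0.42 of that in its richest class, a cluster named osteoclast-like that was also led by T cell genes (Trbc1, Trbc2, Gzma) and granule genes (Prtn3, Elane). Bglap is 1 of the markers that name the class, and with clusters made without the osteoblast and matrix lists its log2 change was -2.03. Without cKO replicate 1, the deep cKO library, 373 genes passed, and without WT(fl/fl) replicate 4 there were 2. Neutrophil genes were lower in these cells too, with S100a9 at a log2 change of -3.15 (SE 0.64, adjusted p = 0.202).

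Fits that took depth into account, added after the planned test, called further genes, and those named from here to the end of the paragraph were chosen after their values were seen. With depth as a covariate and cKO replicate 3 left out, 13 genes passed, and with depth within the shared litter alone 19 genes passed. Ccn1 (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), a matricellular protein and a direct target of YAP and TAZ, fell by 1.59 (adjusted p = 0.00915) and by 1.44 (adjusted p = 0.0168) in these fits, against -0.65 in the planned fit (SE 0.38, adjusted p = 0.837). The range of its adjusted p over the alternatives was 0.00915 to 1. Its levels were 141 ± 33.8, 138 ± 25.0 and 89.2 ± 63.9 CPM, lower in cKO replicates 1 and 2 and not in replicate 3. Within the shared litter Mmp9 rose by 2.76, the secreted chaperone Clu by 2.36, the iron carrier Trf by 2.73 and the cell cycle inhibitor Cdkn1a by 0.96 on the log2 scale. The insulin-like growth factor binding protein Igfbp5 had -1.52 and the netrin receptor Unc5c -2.97 in that fit, and Clu and Ddit4l also differed between the control groups.

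The fixed lists of the mechanical and bone programmes moved little as wholes in osteoblast-like cells in the planned fit. Of 18 measured YAP/TAZ targets, 9 were higher and 9 lower (camera, adjusted p = 0.986), with Gadd45a at 1.05, Amotl1 at 0.72 and Ccn1 at -0.65, and none passed when adjusted over the list alone (within the list, below). From here on, a pair of values in brackets after a list gives its adjusted p with the preset and with an estimated correlation. With depth as a covariate and cKO replicate 3 left out (the depth fit), 12 of 18 were lower and the list fell (0.0188, 0.173). Ccn1 and Amotl2 passed within the list. Leaving out cKO replicate 3 alone gave 0.0243. The list also fell in that fit in endothelial-like and the other tested classes, not in osteoblast-like cells alone. In the depth fit the osteoblast maturation (0.0483, 0.464), osteoblast precursor (0.00530, 0.173) and cytoskeleton and adhesion lists (0.00400, 0.173) passed downwards as well. So did lists outside these programmes: dissociation and stress, 17 of 19 lower, with the immediate-early genes Atf3, Jun, Zfp36 and Dusp1 past the threshold within the list (2.32e-06, 0.173), hypoxia and glycolysis, 21 of 28 (2.07e-05, 0.174), G2 and M phase, 20 of 21 (0.00375, 0.681), and resting and proliferating chondrocyte, 7 of 11 (0.0483, 0.526). The p53 list, 13 of 15 higher (0.0119, 0.526), and epidermal RNA, 3 of 7 higher (0.0483, 0.741), passed upwards. Of 21 osteoblast maturation genes 12 were higher and 9 lower (adjusted p = 0.986). On the voom scale of the test their median log2 change was 0.17 and their mean -0.22, with the test in the direction of the mean, and Bglap alone passed within the list. Its neighbour Bglap2 had -1.93, while Sp7, which encodes Osterix itself, had 0.88. Of 17 osteoblast precursor genes 10 were higher and 7 lower (adjusted p = 0.986), where the test pointed up while on its voom scale the median was -0.03 and the mean -0.06 (edgeR median 0.07), and Cxcl12 alone passed within the list. Of 24 cytoskeleton and adhesion genes 14 were lower (adjusted p = 0.214), and of 16 genes of the BMP, Wnt and Hedgehog response 8 were higher (adjusted p = 0.986), with a test pointing up beside a median of -0.16 and a mean of -0.08 on the voom scale (edgeR median -0.08). The Wnt effector Lef1 in that list, at 0.0471 of its level in lymphocyte-like cells, had 2.03 (SE 0.48) and passed within the list. Of 9 osteoclast regulation genes 6 were lower (adjusted p = 0.986, voom median -0.20, voom mean 0.08), and Mmp9 passed within the list.

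Matrix and hypoxia lists of osteoblast cells passed the camera test with its preset correlation, and none with an estimated one. Of 24 fibrillar collagen and matrix genes 19 were higher, led by Col16a1 and Col6a3, and the list rose (0.0147, 0.609). It turned downwards in the depth fit (adjusted p = 0.509). The call was lost without WT(Osx-cre) replicate 1 (0.0514), cKO replicate 2 (0.231) or cKO replicate 3 (0.591). Of 27 hypoxia and glycolysis genes 20 were lower and the list fell (0.0120, 0.430). In it Ankrd37, a target of hypoxia-inducible factor, had -1.66 (45.1 ± 7.95, 33.7 ± 12.7 and 14.1 ± 10.4 CPM) and passed within the list. That call was lost without WT(Osx-cre) replicate 1 (0.0514) or cKO replicate 1 (0.265). Of 15 p53 and apoptosis genes 12 were higher and the list rose (0.0122, 0.430), except without WT(Osx-cre) replicate 2 (0.0501) or cKO replicate 1 (0.235). Of 24 angiogenic ligands 15 were lower (adjusted p = 0.0943), and Cxcl12, the vasodilator peptide gene Adm at -2.06 and the stem cell factor gene Kitl at -1.14 passed within the list. In the depth fit 18 of 24 were lower and the list passed (0.00623, 0.173), as it did without cKO replicate 3 alone (0.00233). Of 8 endothelial vessel type genes 5 were higher (adjusted p = 0.178).

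The cartilage, cell cycle and control lists of osteoblast cells completed the set. Of 12 hypertrophic chondrocyte genes 8 were higher (adjusted p = 0.148), where Mmp13, a collagenase, had 1.30 and Col10a1, at 0.366 of its level in chondrocyte-like cells, 2.31, and both passed within the list. Of 11 resting and proliferating chondrocyte genes 8 were higher (adjusted p = 0.178), with Col9a2 at 1.5 and Ucma at -1.70. The cartilage RNA list rose, with 7 of 8 higher (0.0208, 0.579). Its member Col9a2 stood at 0.02 of its level in chondrocyte-like cells. The call was lost without WT(Osx-cre) replicate 1 (0.0788), WT(fl/fl) replicate 1 (0.0677) or cKO replicate 2 (0.0715), and the direction turned without cKO replicate 3 (0.591). Of 18 S phase genes 9 were higher (adjusted p = 0.986, with the test pointing up beside a negative median and mean on the voom scale), and of 21 G2 and M phase genes 18 were lower (adjusted p = 0.0586). Of 19 dissociation and stress genes 11 were lower (adjusted p = 0.0586), with the stress-induced factor Atf3 at -1.06. All 5 interferon response genes were lower (adjusted p = 0.178), as were 4 of 5 red blood cell RNA genes (adjusted p = 0.159) and 4 of 5 heavy muscle RNA genes (adjusted p = 0.363). Of 6 epidermal RNA genes 3 were higher (adjusted p = 0.178).

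The pairwise comparisons ask whether each control group alone gives an answer. Against WT(fl/fl), the littermates of cKO replicates 1 and 2, 1 gene passed in osteoblast-like cells, the neutrophil gene Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496, adjusted p = 0.0483). It was seen at 19.0 ± 10.1 CPM in WT(fl/fl) and in none of 3 cKO libraries, whose summed cells allow up to 1.29 CPM. At an unadjusted p under 0.05 there were 438 genes, and DESeq2 called 6. Against WT(Osx-cre) 0 genes passed in edgeR, with 700 at an unadjusted p under 0.05 and 25 by DESeq2. Against WT(fl/fl) the count was 28 without cKO replicate 1, 4 without cKO replicate 2 and 2 without WT(fl/fl) replicate 2. It was 0 without cKO replicate 3, without any 1 WT(Osx-cre) library or without WT(fl/fl) replicate 1, 3 or 4. Against WT(Osx-cre) the count was 523 without cKO replicate 1, 2 without WT(Osx-cre) replicate 4, and 1 without WT(fl/fl) replicate 1 or 4 or cKO replicate 2 or 3.

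Between the control groups 11 genes passed in osteoblast-like cells, 10 higher in WT(Osx-cre) and 1 lower, with 683 at an unadjusted p under 0.05 and 35 by DESeq2. The photoreceptor cilium gene Rpgrip1 rose by 4.55 (adjusted p = 0.00211, 59.9 ± 33.4 against 1.94 ± 1.80 CPM, n = 4 each), the adhesion molecule gene Vcam1 by 1.89, the growth arrest ligand gene Gas6 by 1.96, Clu by 2.59 and Atf3 by 1.46. The hydrolase gene Hddc3 fell by 3.36 (adjusted p = 0.0192, 6.09 ± 3.30 against 63.7 ± 7.59 CPM). Each of the 11 genes lay on its side of every WT(fl/fl) library in 4 of 4 WT(Osx-cre) libraries. In cKO Hddc3 stood at 67.4, 73.5 and 3.76 CPM, low in replicate 3, which shares the single-index kit with WT(Osx-cre). In this comparison genotype label, litter and kit cannot be told apart. The count was 2 without WT(Osx-cre) replicate 1 or 2, 3 without replicate 4 and 5 without replicate 3. It was 5, 4 and 6 without WT(fl/fl) replicates 1, 2 and 3, 39 without cKO replicate 1 and 67 without cKO replicate 3, which enter through the shared estimate of the spread.

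The same question was put to periosteal-like cells, which carry markers of osteoblast precursors, the cells the title names. Top2a, a topoisomerase of dividing cells, stood at 12 ± 2.25 CPM in WT(Osx-cre) (n = 4), 28.0 ± 22.5 in WT(fl/fl) (n = 4) and 116 ± 148 in cKO (n = 3), with 285 CPM in cKO replicate 3. Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331), the collagenase that remodels cartilage at the bone front, stood at 30.7 ± 11.3, 28.0 ± 12.5 and 61.4 ± 17.6 CPM. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p21 inhibitor of the cell cycle, stood at 34.3 ± 3.47, 24.7 ± 6.03 and 53.6 ± 9.21 CPM. Cxcl12 (log2 -0.18) and Postn (-0.30), a matrix protein of the periosteum, differed little.

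No gene passed the edgeR test in periosteal-like cells in cKO against both controls: 0 of 9744, with 570 at an unadjusted p under 0.05 and 2 by DESeq2, the neutrophil genes Retnlg and S100a9. Against WT(fl/fl) alone 0 passed (259 unadjusted, 3 by DESeq2) and against WT(Osx-cre) alone 0 passed (823 unadjusted, 16 by DESeq2). Between the control groups Rpgrip1 passed, up by 5.06 in WT(Osx-cre) (adjusted p = 0.00284, 422 unadjusted, 5 by DESeq2). Without cKO replicate 1 the counts were 993 against both controls, 101 against WT(fl/fl) and 1090 against WT(Osx-cre), and without WT(fl/fl) replicate 1 they were 1 against both and 1 against WT(fl/fl). Without WT(Osx-cre) replicate 4 or cKO replicate 3, 1 gene passed against WT(Osx-cre). Between the controls the count was 10 without cKO replicate 3, 3 without cKO replicate 1 and 0 without WT(fl/fl) replicate 2. With depth as a covariate and cKO replicate 3 left out 15 genes passed, chosen for naming after their values were seen. Mmp13 rose by 1.5 (adjusted p = 0.0171, range 0.0171 to 1 over the fits tabulated for it) and Cdkn1a by 1.03 (adjusted p = 0.0172, range 0.0172 to 1), both higher in 3 of 3 cKO libraries than the control means. The Mmp13 level was 0.06 of that in osteoblast-like cells, and the sign turned to -0.36 with clusters made without the osteoblast and matrix lists. In that clustering cKO replicate 1 alone of the cKO libraries kept enough periosteal-like cells for the fit (386, against 1 and 0). The matrix gene Fbln2 fell by 1.30 and the lipid carrier gene Apod by 1.28 in the depth fit.

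Of the lists, 8 passed camera in periosteal cells, none with an estimated correlation. G2 and M phase rose, 15 of 15 (1.33e-08, 0.160), 10 past the threshold within the list. Top2a (log2 2.80) and Mki67 (2.95) led it, at 0.21 and 0.14 without cKO replicate 3. An unnamed cycling, periosteal-led cluster held 719 cells, 1 from cKO replicate 3, so naming may add to the rise. The S phase list rose with 17 of 19 higher (3.07e-05, 0.160), as did the hypertrophic chondrocyte list with 11 of 11, led by Mmp13 and Sp7 (3.87e-05, 0.0644). The osteoblast maturation list passed upwards with 11 of 16 members higher, of which Smpd3 (1.89) and Sp7 (1.35) alone passed within the list and stood at 0.0400 and 0.274 of their level in osteoblast-like cells (0.0390, 0.160), as did p53 and apoptosis, 11 of 13 (0.0390, 0.160), and epidermal RNA, 6 of 7 (0.0390, 0.581). Hypoxia and glycolysis fell, 20 of 27 (0.0390, 0.495), and heavy muscle RNA 7 of 7 (0.0173, 0.495). YAP/TAZ targets were split 10 to 10 (adjusted p = 0.922), with Ccn2 at -1.01 and Ccn1 at 0.06. In the depth fit 16 of 20 were lower and the list fell (0.000306, 0.0771), as it did without cKO replicate 3 alone (0.00183). Dissociation and stress fell in the depth fit too, 17 of 19, with Fosb and Egr1 past the threshold within the list (0.000308, 0.158), as did osteoblast precursor, 15 of 18 (0.00333, 0.0867), and the BMP, Wnt and Hedgehog response, 13 of 16 (0.00160, 0.153). Red blood cell RNA, 5 of 5 (0.000308, 0.220), and epidermal RNA, 7 of 7 (0.00160, 0.348), rose in it. It called 5 more lists, all upwards, and none with an estimated correlation. The planned G2 and M, S phase and hypertrophic calls held with any library left out, under the same naming. Osteoblast maturation was lost without WT(Osx-cre) replicate 1 (0.0576) or cKO replicate 1 (0.265). Hypoxia was lost without WT(Osx-cre) replicate 1 (0.0587), WT(fl/fl) replicate 2 (0.0622), or cKO replicate 1 (0.0664) or 3 (0.588). The p53 list was lost without WT(Osx-cre) replicate 1 (0.0576), WT(fl/fl) replicate 3 (0.0563) or 4 (0.0616), or cKO replicate 1 (0.521) or 3 (0.0582), and heavy muscle RNA without cKO replicate 3 (0.799). Epidermal RNA was lost without WT(Osx-cre) replicate 1 (0.0587) or 3 (0.0793), WT(fl/fl) replicate 2 (0.329), 3 (0.0779) or 4 (0.0723), or cKO replicate 1 (0.701). Red blood cell RNA, 4 of 5 higher in edgeR but with a voom median of -0.99, did not pass (adjusted p = 0.212).

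In chondrocyte-like cells, with 0, 0 and 3 Cre UMIs in cKO, 29 of 30 hypoxia and glycolysis genes were lower against both controls. Bnip3, a mitophagy receptor, stood at 644 ± 82.0 CPM in WT(Osx-cre) and 329 ± 79.5 in WT(fl/fl) (n = 4 each), and nearer the latter in cKO, 277 ± 90.1 (n = 3). Car9, Ero1l and Bnip3l had log2 changes of -0.73, -0.48 and -0.67. Col10a1, the collagen of hypertrophic cartilage, had 0.77 (SE 0.42, adjusted p = 0.742). No gene passed the edgeR test against both controls: 0 of 11559, with 774 at an unadjusted p under 0.05, and 3 by DESeq2. Without cKO replicate 1 the count was 1292, and it was 1 without cKO replicate 2 or 3. With depth as a covariate and cKO replicate 3 left out, 14 passed.

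The list tests in chondrocyte-like cells called 7 of the lists for chondrocyte sums, none with an estimated correlation. The hypoxia and glycolysis list fell (1.03e-05, 0.333) and passed with each library left out. The osteoblast precursor list passed upwards with 15 of 18 higher, the Hedgehog targets Gli1 and Ptch1 first and no member past the threshold (0.0173, 0.418), as did G2 and M phase, 17 of 21 (0.0237, 0.737), and epidermal RNA, 7 of 7 (0.000307, 0.418). Interferon response fell, 7 of 7, with Bst2 at -1.14 (0.0195, 0.418). Dissociation and stress fell, 13 of 19 (0.00918, 0.418), and heavy muscle RNA 7 of 8 (0.0146, 0.616). YAP/TAZ targets, 11 of 20 higher, did not pass (adjusted p = 0.804). In the depth fit 15 of 20 were lower and the list fell (0.00409, 0.317), as it did without cKO replicate 3 alone (0.00977). Dissociation and stress, 16 of 19 with Atf3 and Fosb past the threshold within the list (0.000442, 0.317), fell in the depth fit as well. Rising in it were red blood cell RNA, 5 of 5 with all 5 past that threshold (1.69e-05, 0.317), and epidermal RNA, 7 of 7 with 4 past it (9.65e-06, 0.317). It called 4 more lists, and none with an estimated correlation. In the planned fit without cKO replicate 1 the precursor (0.147), G2 and M (0.422), interferon (0.0840), stress (0.0840) and epidermal (0.328) calls were lost. Without cKO replicate 2 the G2 and M (0.372), interferon (0.116) and stress (0.372) calls were lost. Without cKO replicate 3 the precursor (0.540) and interferon (0.691) calls were lost and heavy muscle RNA passed in the other direction (0.0365). The G2 and M call was also lost without WT(Osx-cre) replicate 2 (0.110) or WT(fl/fl) replicate 1 (0.148).

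The title's question on vessels was put to blood endothelial-like cells, which the Cre is not meant to reach. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), an interferon-induced ubiquitin-like protein, stood at 214 ± 53 CPM in WT(Osx-cre) (n = 4), 69.4 ± 26.2 in WT(fl/fl) (n = 4) and 43.4 ± 7.89 in cKO (n = 3). The VEGF receptor gene Kdr (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458) stood at 291 ± 10.2, 302 ± 49.2 and 416 ± 265, and Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293), the receptor of Cxcl12, at 13.8 ± 2.06, 12.7 ± 4.84 and 25.9 ± 23.6. The log2 changes were 0.49 (SE 0.32) for Kdr and 0.86 (SE 0.45) for Cxcr4, each with an adjusted p of 1, and without cKO replicate 3 they were -0.17 and -0.31. The neutrophil gene Retnlg was the 1 gene of 11731 to pass in edgeR (log2 -4.38, SE 0.50, adjusted p = 0.00384), at 15.6 ± 3.69, 24.7 ± 7.46 and 0.356 ± 0.617 CPM and lower in 3 of 3 cKO libraries than in any control. At an unadjusted p under 0.05 there were 364 genes, and DESeq2 called 6, among them Isg15 (log2 -1.40, adjusted p = 0.0144). The edgeR count was 9 without cKO replicate 1, where Retnlg itself missed the threshold (adjusted p = 0.0516), and 2 without cKO replicate 3. The fit with depth as a covariate and cKO replicate 3 left out called 19 genes, among them, chosen after their values were seen, the lymphatic chemokine gene Ccl21a, which rose by 2.32 and stood at 0.000726 of its level in lymphatic endothelial-like cells.

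The endothelial vessel type list holds markers of arterial, tip and sinusoidal cells beside general endothelial genes such as Pecam1. Among its 25 measured genes 19 were higher and 6 lower, and neither the list (adjusted p = 0.276) nor any member within the list passed. In the depth fit 22 of 26 were lower and the list fell (4.67e-07, 0.203), as it did without cKO replicate 3 alone (5.72e-06). The Notch pathway genes Notch1 at -0.58 and Dll4 at -0.51 and the receptor Flt1 at -0.44 were past the threshold within the list. In that fit the lists of RNA from other classes moved as well: epidermal RNA rose, 7 of 7 with all 7 past that threshold (2.25e-07, 0.257), as did red blood cell RNA, 5 of 5 with 4 past it (0.000308, 0.257), and osteoblast precursor, 14 of 17 with Cxcl12, Thy1 and Twist1 past it upwards and Aspn downwards (0.00319, 0.257). Dissociation and stress, 17 of 19 (0.000270, 0.286), and YAP/TAZ targets, 15 of 20 (0.0434, 0.257), fell. This fit called 3 more lists upwards and 5 downwards, and none with an estimated correlation. The planned fit called 10 lists for endothelial sums, none with an estimated correlation, and for lists of genes of other classes free RNA was not told apart from expression. Rising were osteoblast precursor, 16 of 17 (8.75e-07, 0.332), fibrillar collagen and matrix, 19 of 23 (0.000298, 0.537), hypertrophic chondrocyte, 8 of 9 (0.0104, 0.435), and osteoclast regulation, 4 of 8 (0.0391, 0.269). So were S phase, 14 of 20 (0.0167, 0.269), G2 and M phase, 16 of 21 (0.0144, 0.335), and epidermal RNA, 7 of 7 with the keratins Krt5, Krt14 and Krt15 past the threshold within the list, at 0.00669, 0.00605 and 0.00463 of their level in keratinocyte-like cells (3.94e-07, 0.253). Falling were hypoxia and glycolysis, 26 of 29 (0.000403, 0.253), interferon response, 10 of 10 (3.66e-05, 0.253), and dissociation and stress, 13 of 19 (0.0110, 0.403). Without cKO replicate 1 the hypoxia (0.0677), osteoclast (0.446), S phase (0.816), G2 and M (0.794), interferon (0.0724), stress (0.125) and epidermal (0.0719) calls were lost. Without cKO replicate 2 the collagen (0.0990), hypertrophic (0.272), osteoclast (0.121), G2 and M (0.0633) and stress (0.438) calls were lost, and without cKO replicate 3 the collagen (0.263) and hypertrophic (0.128) calls. Osteoclast regulation was also lost without WT(Osx-cre) replicate 1 (0.0800) or WT(fl/fl) replicate 2 (0.229), hypertrophic chondrocyte without WT(fl/fl) replicate 2 (0.0502) and G2 and M without WT(fl/fl) replicate 4 (0.0511).

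Fibroblast-like cells were compared as a class outside the Osterix lineage. Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962), a transporter of small peptides, rose by 1.96 on the log2 scale (SE 0.27, adjusted p = 0.0310), from 1.73 ± 0.450 CPM in WT(Osx-cre) (n = 4) and 2.78 ± 0.825 in WT(fl/fl) (n = 4) to 8.45 ± 1.27 in cKO (n = 3), higher in 3 of 3 cKO libraries. Retnlg fell by 4.55 (SE 0.56, adjusted p = 0.0202), from 14.7 ± 3.83 and 17.6 ± 4.38 to 1.13 ± 1.44 CPM. These were the 2 genes of 14468 to pass, with 859 at an unadjusted p under 0.05 and 3 by DESeq2. The count was 456 without cKO replicate 1 and 5 without cKO replicate 3. It was 1 without WT(Osx-cre) replicate 2, WT(fl/fl) replicate 1 or cKO replicate 2, and 0 without WT(Osx-cre) replicate 1 or 4 or WT(fl/fl) replicate 2, 3 or 4. The Slc15a2 call was also lost with the kit as a covariate (adjusted p = 0.0880), within a range of 2.57e-05 to 1 over the alternatives.

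**Figure D2:**
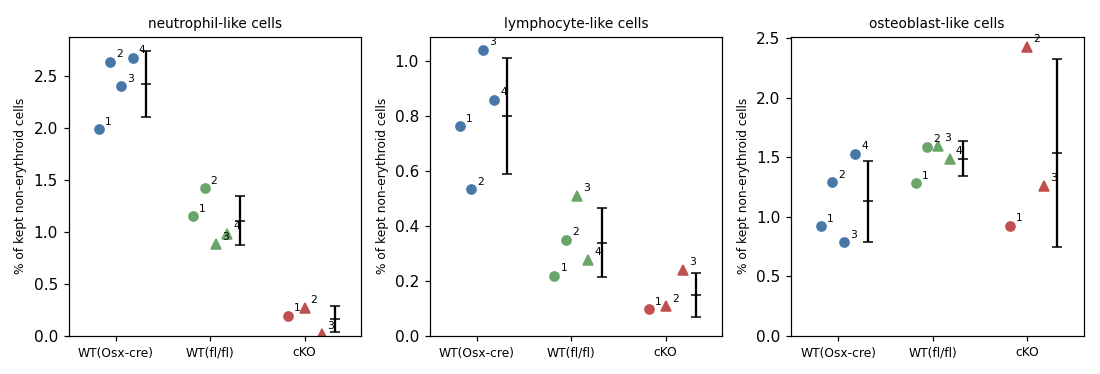
Share of neutrophil-like, lymphocyte-like and osteoblast-like cells (vertical axes, percent of kept cells other than erythroid-like) in each library, by group on the horizontal axis; triangles are libraries under 40 M UMIs, circles the others, and black marks the mean ± SD. The neutrophil-like share averaged 0.160% in cKO against 2.42% and 1.11% in the controls.

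The share of each class among kept cells asks whether the make-up of the dissociated limb differed. Neutrophil-like cells made up 2.42% ± 0.317 of the cells in WT(Osx-cre) (n = 4), 1.11% ± 0.235 in WT(fl/fl) (n = 4) and 0.160% ± 0.128 in cKO (n = 3), and 3 of 3 cKO libraries lay below every control. The difference of -1.61 percentage points had a two-sided exact permutation p of 0.0121, which did not pass over 18 classes (adjusted p = 0.218). Lymphocyte-like cells made up 0.799% ± 0.211, 0.339% ± 0.126 and 0.148% ± 0.0802 (exact p = 0.0424, adjusted p = 0.255) and macrophage-like cells 4.74% ± 0.676, 4.89% ± 0.632 and 5.92% ± 0.615 (exact p = 0.0242, adjusted p = 0.218). No class passed the permutation test, in which the number of splits does not let a single class pass over 18 classes; edgeR on cell counts called neutrophil-like (log2 -3.32, adjusted p = 0.00186) and lymphocyte-like cells (log2 -1.84, adjusted p = 0.00959). Pairwise, lymphocyte-like shares gave an exact p of 0.114 against WT(fl/fl), inside whose range cKO replicate 3 lay, and 0.0286 against WT(Osx-cre) and between the controls, and neutrophil-like shares 0.0286 in all 3. Within the shared litter the differences were -0.88 points for neutrophil-like (exact p = 0.0667, the smallest that 15 splits allow) and -0.237 for lymphocyte-like cells (0.133). Osteoblast-like cells made up 1.13% ± 0.340, 1.49% ± 0.147 and 1.54% ± 0.790 (exact p = 0.467), a difference of 0.228 points that was 0.0922 with clusters made without the osteoblast and matrix lists. It turned to -0.112 when the clusters left unnamed for tied markers were counted under their leading class, which gave 1.78% ± 0.513, 2.00% ± 0.541 and 1.78% ± 0.596 (exact p = 0.818). Periosteal-like cells made up 2.44% ± 0.776, 2.75% ± 0.952 and 3.74% ± 0.645 (exact p = 0.0606), a difference of 1.14 points that turned to -1.02 with those clusters. There the name reached 386, 1 and 0 cells of the cKO libraries and 0 and 5 of WT(fl/fl) replicates 3 and 4, so that the 4 shallow libraries nearly lost the class. Blood endothelial-like cells made up 6.75% ± 0.841, 6.55% ± 1.94 and 6.33% ± 2.85 (exact p = 0.861).

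**Figure D3:**
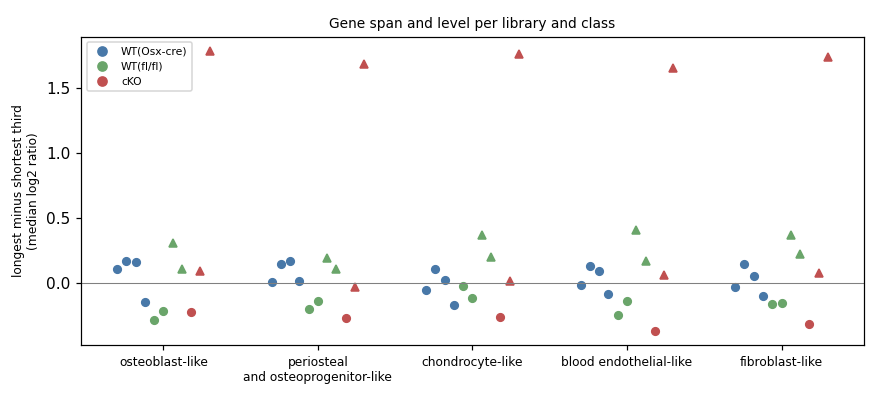
Median log2 ratio of each library to the mean of the others in the longest tertile of genes minus that in the shortest tertile (vertical axis), for 5 cell classes on the horizontal axis; each point is a library, coloured by group, with triangles for libraries under 40 M UMIs. The cKO replicate 3 lies between 1.66 and 1.79 in the 5 classes, and all other libraries between -0.37 and 0.41.

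As a measured fact beside all of these comparisons, cKO replicate 3 stood apart. In its osteoblast-like cells genes with a span of at least 38.5 kb were raised over genes of at most 12 kb by 1.79 on the log2 scale, and in the other 4 classes by 1.66 to 1.77, while the remaining libraries lay between -0.37 and 0.41. Its library-wide level of Xist was 1988 CPM, against 290 and 389 in the libraries with Xist among the rest, and Yap1 stood at 67.5 CPM against 10.2 to 22.4. Gm42418 took 186531 CPM of its UMIs, against 4676 to 36546 elsewhere, and the nuclear RNA Malat1 stood at 49610 CPM, inside the 38830 to 66344 of the other libraries. The neutrophil gene S100a9 stood at 61.5, 158 and 6.55 CPM in the cKO libraries as a whole, against 487 to 1689 in the controls.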

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

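In this part the tests of embryo sex and library kit for cKO replicate 3, of litter and low depth for the neutrophil genes, both tests of the Cre UMIs and all counts over other splits of the libraries were chosen only after the result was seen.

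The library cKO replicate 3 carried more RNA of long genes than any other library, in each of the 5 classes. More RNA from long, unspliced transcripts, as from leaking nuclei or broken cells, stays open: the longest tertile of genes lay at least 1.66 on the log2 scale above the shortest tertile in every class, but this prediction restates the pattern, and no unspliced reads were measured. Of nuclear RNAs, Xist was raised, at 1988 CPM against 290 and 389 in the other libraries with it, and Malat1 was not, at 49610 CPM against 38830 to 66344, so a nuclear source was not decided. Low depth is argued against by the other 3 shallow libraries, whose mean was 0.225 and whose highest was 0.373 in fibroblast-like cells, where cKO replicate 3 stood at 1.74; the bound set in advance, a mean under 0.2, was narrowly missed, and the reading rests on the comparison with cKO replicate 3, chosen after the value was seen. Embryo sex is argued against by WT(Osx-cre) replicate 1 and WT(fl/fl) replicate 1, the other libraries with Xist and with at most 0.0149 CPM of the Y-linked Ddx3y, which lay between -0.28 and 0.11 over the 5 classes. The single-index kit alone is argued against by the 4 WT(Osx-cre) libraries made with it, which lay between -0.16 and 0.17, and the genotype label alone by cKO replicates 1 and 2, between -0.37 and 0.10. Its litter, shared with no other library, and its preparation remain open and were not tested.

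Neutrophil genes were lower in every tested class of the cKO libraries, beside a lower neutrophil-like share. Free RNA that follows the number of neutrophil-like cells may carry these genes into other classes: within a library the highest class level of S100a9 was 1.98 times the lowest in the median, where a value under 3 was predicted. Litter is argued against for the share, since in the litter with both genotypes the highest cKO share was 0.304 of the lowest WT(fl/fl) share. Low depth is argued against by the same ratio, 0.304, between the shallow cKO library of that litter and the lower shallow WT(fl/fl) library. A biological difference in neutrophil number between the genotypes stays open as a hypothesis, as do differences between embryos in red cell lysis and blood content, which were not tested.

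Cre UMIs appeared 43 times in the cKO libraries together, a transgene read outside the main measurement, and 0 times in osteoblast-like cells of the libraries labelled WT(Osx-cre). Too few UMIs is argued against, since 27.2 Cre UMIs would be expected there at the lowest cKO rate. An embryo or transgene other than the label states cannot be told apart from a transgene that is not transcribed or is built without the searched sequence, since each gives the 0 that was seen. No biological explanation was tested.

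GFP UMIs, also outside the main measurement, numbered 64 in WT(fl/fl) replicate 3, 149 in WT(fl/fl) replicate 4 and 93 in cKO replicate 2, the 3 shallow dual-index libraries. In osteoblast-like cells GFP stood at 62.6, 62.8 and 69.7 CPM in these libraries (18, 21 and 20 UMIs), and at 0 to 1.22 CPM in the other WT(fl/fl) and cKO libraries. The level in the 3 shallow libraries, close in a pair of controls to that of a cKO library and above that of the periosteal-like, chondrocyte-like and other kept cells, raises the question whether these 2 controls carry the Osx-cre construct, if that holds GFP, which the labels do not state. The Cre UMIs go against this: at the rate of cKO replicate 2 the 2 controls together would hold 6.50 in osteoblast-like cells and 26.8 over all barcodes, at that of cKO replicate 1, 2.66 and 4.89, and 0 were seen. The cKO replicates 1 and 3 hold Cre with little or no GFP. The libraries labelled WT(Osx-cre), which hold almost no Cre UMIs, limit this reading. Where the GFP RNA came from was not tested, and the comparisons with WT(fl/fl) rest on these labels.

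In 10 of 96 groups of 4 libraries 1 library stood apart from the rest of its group, by a gap that took more of the group's range than the 95% critical value of Dixon for 4 samples allows, where chance sets apart about 1 in 20 groups. In WT(Osx-cre) this ratio was 0.853 for the share of blood endothelial-like cells (replicate 1 low), 0.901 for the share of mast cell-like cells (replicate 4 high), and 0.856 and 0.841 for Yap1 in blood endothelial-like cells (replicate 2 low) and fibroblast-like cells (replicate 1 high). It was 0.943 for Vegfa in osteoblast-like cells (replicate 4 low) and 0.955 for Vegfa in endothelial-like cells (replicate 1 high). In WT(fl/fl) it was 0.852 for the share of blood endothelial-like cells (replicate 2 high) and 0.930 for Yap1 in blood endothelial-like cells (replicate 1 high). It was 0.853 for Wwtr1 in osteoblast-like cells and 0.850 for Kdr in chondrocyte-like cells, where the shallow replicate 3 was low and high.

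Other splits of the libraries into groups of the same sizes show whether chance can be excluded for the gene counts. For cKO against both controls 9 of 100 splits gave at least the real 1 gene in endothelial-like cells (highest other 2087) and 6 of 100 at least the real 2 in fibroblast-like cells (highest other 2982), so chance cannot be excluded there. Where the real count is 0 every split gives at least as many, so the splits decide nothing: this was so for 100 of 100 in osteoblast-like cells (real 0, highest other 759), periosteal-like cells (real 0, highest other 1780) and chondrocyte-like cells (real 0, highest other 3187). The highest splits set WT(fl/fl) replicates 3 and 4 with cKO replicate 3 against the rest and call many times the real count, which points to a structure of the samples. These are 3 of the 4 shallow libraries, with cKO replicate 2 on the other side, and depth was not separated from the shift of cKO replicate 3 itself. The real counts with depth as a covariate and cKO replicate 3 left out were 13, 15, 14, 19 and 15 in the order osteoblast, periosteal, chondrocyte, endothelial and fibroblast.

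Of 35 splits in the pairwise comparisons of osteoblast-like cells, 6 gave at least the real 1 gene for cKO against WT(fl/fl), so chance cannot be excluded (highest other 1324, with WT(fl/fl) replicates 1 and 2 and cKO replicate 1, the deep libraries, on one side). For WT(Osx-cre) against WT(fl/fl) only the real split gave 11 genes (highest other 1). As 1 of 35 is the least possible, chance is not excluded, and litter and kit are tied to the group. In periosteal-like cells 2 of 35 gave at least the real 1 between the control groups (highest other 1), so chance cannot be excluded. Nothing is decided where the real count is 0, which all 35 splits reach: osteoblast-like cells against WT(Osx-cre) (highest other 1), periosteal-like cells against WT(fl/fl) (highest other 2039, the same deep libraries on one side) and periosteal-like cells against WT(Osx-cre) (highest other 1).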

How the results depend on the processing

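In this part the fits that handle depth (without the 3 shallow dual-index libraries, on deep libraries alone, with depth as a covariate), the gene counts and lists after clustering without the osteoblast and matrix lists, and the shares among named cells, without the 3 shallow dual-index libraries and with clusters of tied markers counted were chosen only after the result was seen. All other alternatives were planned. Where no cause is named below, the cause was not tested.

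Counts of genes past the threshold are given first for the test, the filter and the depth fits, in the order osteoblast, periosteal, chondrocyte, endothelial and fibroblast for cKO against both controls (0, 0, 0, 1 and 2 in the planned test). Then follow, in the osteoblast and then the periosteal class, cKO against WT(fl/fl) (1 and 0), cKO against WT(Osx-cre) (0 and 0) and WT(Osx-cre) against WT(fl/fl) (11 and 1). The DESeq2 Wald test called 14, 2, 3, 6 and 3 genes against both controls, then 6 and 3, 25 and 16, and 35 and 5. Without a filter on low counts edgeR called 60, 23, 9 and 4 in the same classes, then 48 and 8, 114 and 56, and 136 and 20. On deep libraries alone, with a lone cKO library that is assumed to vary like the other groups, edgeR called 11, 8, 8, 16 and 4, then 14 and 4, 27 and 181, and 597 and 436. The fit with depth as a covariate and cKO replicate 3 left out called 13, 15, 14, 19 and 15, then 16 and 7, 43 and 283, and 579 and 406. In the shared litter with depth as a covariate it called 19, 3, 4, 8 and 7, then 19 and 3 against WT(fl/fl).

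Other settings moved single counts. Thinning to the smallest total gave 0 in the endothelial and fibroblast classes, 0 osteoblast genes against WT(fl/fl) and 0 between the control groups in both classes, by its construction with fewer counts. Leaving out the 3 shallow dual-index libraries gave 0 endothelial and 0 fibroblast genes and 0 between the control groups in both classes, with fewer libraries. The shared litter alone, with 4 and 2 libraries, gave 0 endothelial, 0 fibroblast and 0 osteoblast genes against WT(fl/fl). The stricter cell filter gave 0 endothelial and 1 fibroblast gene, 2, 6 and 21 osteoblast genes against WT(fl/fl), against WT(Osx-cre) and between the control groups, and 0 periosteal genes between the control groups. With doublets kept, 3 osteoblast and 0 fibroblast genes passed against both controls, 0 and 14 osteoblast genes against WT(fl/fl) and WT(Osx-cre), and 0 periosteal genes between the control groups. Leiden resolution 2 gave 1 osteoblast, 3 periosteal and 1 fibroblast gene, and 4 periosteal genes against WT(Osx-cre). The graph with neighbours from each library gave 1 fibroblast gene, 0 osteoblast genes against WT(fl/fl), and 23 and 0 genes between the control groups. DESeq2 size factors gave 0 osteoblast genes against WT(fl/fl). Clustering without the osteoblast and matrix lists gave 6 periosteal (with a lone cKO library) and 1 fibroblast gene, 0 and 2 osteoblast genes against WT(fl/fl) and WT(Osx-cre), 1 and 95 periosteal genes in the same order, and 166 between the control groups. With the kit as a covariate 1 fibroblast gene, 0 osteoblast genes against WT(fl/fl), and 2501 osteoblast and 3444 periosteal genes against WT(Osx-cre) passed. By its construction that last fit sets cKO replicate 3, the lone cKO library of its kit, against WT(Osx-cre).

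The replicate numbers do not pair the embryos. Deviations from the group means correlated over 0.1 in 2, 3, 5, 4 and 2 of 10 pairs with the same number (osteoblast, periosteal, chondrocyte, endothelial, fibroblast) and in 8, 7, 10, 9 and 9 of 30 other pairs. With the replicate number as a block 0 fibroblast genes passed (Slc15a2 in fibroblast-like cells had an adjusted p of 0.351, range over alternatives 2.57e-05 to 1), 3 osteoblast and 1 periosteal gene passed against WT(Osx-cre), 27 lists passed, and 2 classes passed in edgeR on cell counts, as without the block.

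Leaving out 1 library in turn gave 0 to 373 osteoblast, 0 to 993 periosteal, 0 to 1292 chondrocyte, 1 to 9 endothelial and 0 to 456 fibroblast genes against both controls. It gave 0 to 28 and 0 to 101 against WT(fl/fl), 0 to 523 and 0 to 1090 against WT(Osx-cre), and 2 to 67 and 0 to 10 between the control groups. The highest value came without cKO replicate 1, the deep cKO library, except between the control groups, where it came without cKO replicate 3. The count without each library that moved it stands with the results above. The 1 osteoblast gene against WT(fl/fl) was among those called without WT(fl/fl) replicate 2 (2 genes) or cKO replicate 2 (4). It was not among the 28 called without cKO replicate 1, and without any other single library 0 genes passed. Yap1 and Wwtr1 passed in 0 to 1 class, Yap1 in periosteal-like cells without cKO replicate 1. Shares gave 0 to 0 classes, in a test with too few splits for 1 class to pass alone.

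Of the list tests, 29 passed with the preset correlation, 0 with an estimated correlation, 2 with fry and 16 (without cKO replicate 1) to 38 (without cKO replicate 3) with 1 library left out. Depth as a covariate with cKO replicate 3 left out gave 44 (38 without that library alone), and 0 with an estimated correlation added. Both depth fits turned the direction of 4 lists: fibrillar collagen and matrix in osteoblast cells (adjusted p = 0.509 and 0.902, range over alternatives 0.000416 to 0.902), cartilage RNA in osteoblast cells (0.340 and 0.833, range 0.000156 to 0.833), hypoxia and glycolysis in periosteal cells (0.943 and 0.970, range 0.0107 to 0.970) and heavy muscle RNA in chondrocyte cells (0.0906 and 0.570, range 0.00738 to 0.616). Clustering without the osteoblast and matrix lists, which left a lone cKO library in that class, turned osteoblast maturation (0.966, range 0.00857 to 0.966) and heavy muscle RNA (0.916, range 0.00144 to 0.916) in periosteal cells. Without cKO replicate 3 cartilage RNA in osteoblast cells (0.591, against 0.00527 without cKO replicate 1) and heavy muscle RNA in chondrocyte cells (0.0365) turned. Hypoxia and glycolysis in chondrocyte cells and S phase in periosteal cells kept direction and passed in 15 of 18 alternatives, none against WT(fl/fl) alone.

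Several log2 changes that did not pass in the planned test turned sign in the shared litter alone, on deep libraries alone, with depth as a covariate without cKO replicate 3, and with depth as a covariate in the shared litter, given in this order. Yap1 in osteoblast-like cells (0.24) came to -0.81, -0.45, -0.58 and -0.78, Yap1 in periosteal-like cells (0.62) to -0.44, -0.45, -0.40 and -0.46, and Yap1 in chondrocyte-like cells (0.51) to -0.88, -0.50, -0.66 and -0.77. Yap1 in endothelial-like cells (0.57) came to -0.39, -0.43, -0.32 and -0.52, and Yap1 in fibroblast-like cells (0.39) to -0.31, -0.27, -0.25 and -0.32. Cxcr4 in endothelial-like cells (0.86) came to -0.19, -0.36, -0.32 and -0.16, Kdr in endothelial-like cells (0.49) to -0.20, -0.068, -0.15 and -0.19, and Vegfa in osteoblast-like cells (0.32) to -0.53, -1.06, -0.82 and -0.62. Clustering without the osteoblast and matrix lists, with a lone cKO library in the periosteal class, gave -0.37 and -0.58 for Yap1 in osteoblast-like cells and Yap1 in periosteal-like cells and -0.32 for Vegfa in osteoblast-like cells. Each of these turned without cKO replicate 3 as well: with 1 library left out they ran from -0.61 to 0.66, -0.41 to 1.10, -0.68 to 0.93, -0.27 to 1.10 and -0.23 to 0.68 for Yap1 in the order above, from -0.31 to 1.54 for Cxcr4, from -0.17 to 0.74 for Kdr and from -0.71 to 0.86 for Vegfa.

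Wwtr1 in osteoblast-like cells stayed negative under all 27 alternatives (-1.46 to -0.82), as did Wwtr1 in chondrocyte-like cells (-0.59 to -0.18). Wwtr1 in fibroblast-like cells, at -0.07, came to 0.0019 in the shared litter, 0.024 with the stricter filter, 0.027 on deep libraries alone, 0.014 with depth as a covariate without cKO replicate 3 and -0.18 to 0.0026 with 1 library left out (highest without cKO replicate 2). Thinning gave 0.033 for Wwtr1 in endothelial-like cells and 0.26 for Wwtr1 in periosteal-like cells, and the balanced graph 0.071 for the latter. Bglap in osteoblast-like cells stayed negative in 27 of 27 alternatives (-3.64 to -1.09) and passed in 3, as did Cxcl12 in osteoblast-like cells (-2.72 to -1.71, 3). Ccn1 in osteoblast-like cells passed in 2 (-1.68 to -0.27). Retnlg kept its call in 22 of 27 in endothelial-like cells (-9.13 to -3.62) and 16 of 27 in fibroblast-like cells (-4.97 to -2.58), and Slc15a2 in 6 of 26 in fibroblast-like cells (1.54 to 2.13).

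No class share passed the exact test in any of its alternatives, which says nothing about stability: over 18 classes no class alone can pass with so few splits, whatever its share. edgeR on cell counts called 2 classes, neutrophil-like and lymphocyte-like cells, both lower, and 2 with the kit as a covariate. The change in the share of periosteal and osteoprogenitor-like cells, 1.14 in percentage points, came to -1.02 after clustering without the osteoblast and matrix lists. The share of osteoblast-like cells (0.228) came to -0.141 without the 3 shallow dual-index libraries, to -0.112 with clusters of tied markers counted under their leading class, and ran from -0.218 (without cKO replicate 2) to 0.535 with 1 library left out.

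Shallow libraries hold fewer UMIs per cell, so their sums measure fewer genes well: in osteoblast-like cells WT(fl/fl) replicate 3 gave 287352 UMIs from 125 cells and WT(Osx-cre) replicate 3 gave 826001 from 84. The periosteal class lost shallow libraries with under 20 cells under the stricter filter, with doublets kept, in the balanced graph and in the clustering without osteoblast lists. The endothelial class lost 1 under the stricter filter and the fibroblast class 1 WT(fl/fl) and 1 cKO library with doublets kept. The shared litter holds no WT(Osx-cre) library and gives no value against it, Yap1 in osteoblast-like cells and Slc15a2 had no value in thinned counts, and the kit covariate was not run between the control groups.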

Other observations

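The genes of this part, with their tests, were chosen only after their values were seen; the shares belong to a planned comparison.

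Hddc3 (ENSMUSG00000030532) stood in fibroblast-like cells at 9.55, 9.89, 8.44 and 7.94 CPM in WT(Osx-cre) replicates 1 to 4 and at 57.1, 68.1, 69.4 and 55.4 in WT(fl/fl). In cKO it stood at 70.2 and 91.7 in replicates 1 and 2 and at 6.03 in replicate 3, so its level followed the index kit, to which the litters are tied. Rpgrip1 (ENSMUSG00000057132) was highest in WT(Osx-cre), at 55.5, 64.8, 138 and 35.5 CPM in fibroblast-like cells against 2.73, 2.67, 2.57 and 7.42 in WT(fl/fl) and 3.49, 15.6 and 6.98 in cKO. Between the control groups Rpgrip1 differed by a log2 change of 4.40 in fibroblast-like cells (adjusted p = 0.0114), 4.74 in endothelial-like cells (0.0160) and 4.39 in chondrocyte-like cells (0.0121), higher in 4 of 4 libraries each.

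Classes outside the lineages compared above showed wide spread within groups. Keratinocyte-like cells made up 6.10% ± 2.41 of the kept cells in WT(Osx-cre) (n = 4), 3.68% ± 4.01 in WT(fl/fl) (n = 4) and 7.35% ± 1.00 in cKO (n = 3). The cluster named osteoclast-like, a mixture with lymphocyte genes, made up 0.736% ± 0.393, 1.09% ± 0.425 and 0.569% ± 0.206. Synovial and articular-like cells made up 2.16% ± 0.785, 1.25% ± 1.42 and 2.17% ± 2.21, and were nearly missing from the 3 shallow dual-index libraries. None of these differences passed the exact permutation test.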
